A study of Mus musculus with 4 samples.

How the data were processed

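Gene expression was measured on 4 Agilent whole mouse genome oligonucleotide arrays in the 2-colour format. Per the labels' protocols, total RNA was purified with Trizol, 200 ng was amplified and labelled with Cy3 or Cy5, and 825 ng of each labelled cRNA was hybridised. Each array held RNA of 15p cells in one dye and of 0p cells in the other. The sample titles number 2 biological replicates, and each was hybridised as a pair of arrays with the dyes exchanged. The direction of every ratio was taken from the dyes in the labels. The labels list Wnt-3a as the treatment of both RNAs. They do not say whether the replicates came from separate animals, so p-values cannot be taken to cover a spread between animals. They rest on the spread between these 2 replicates, moderated over all genes (prior degrees of freedom 8.89, residual 1).

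The deposited scanner files hold mean spot intensity and local background intensity in each dye, which per the file headers were extracted with Agilent Feature Extraction 10.7.3.1, a version also given in the submitters' processing notes. Processed intensity in the same deposited files was background-subtracted, spatially detrended and dye-normalised within each array, per the file headers. The deposited log10 ratio is the log10 of Cy5 over Cy3 processed intensity, per the file headers. Other columns are flags of 0 or 1 for spots well above background, saturated or irregular, set by the software per the file headers. The value table of the series holds the same deposited log10 ratios of Cy5 over Cy3, not turned for the dye swap: it differed from the arrays' own ratios by at most 0.0045, and each column's median was 0. Its scale and direction were found by this comparison, and it was used only as an alternative.

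The values were analysed in R 4.3.3 with limma 3.58.1, and files were read with the data.table package (version 1.17.8). Mean spot intensities were corrected with normexp on all spots (offset 50) and normalised within each array by loess, with control spots at weight 0. Control spots and spots flagged as irregular were then left out (154 to 286 of 43020 spots an array); no spot was saturated. Spots of one probe were averaged, which left 39429 probes. Symbols were taken from the RefSeq table of the GRCm38.p6 assembly through the probe's transcript accession, which matched for 26055 probes, 3358 of them under another symbol than in the files. The other probes kept the name in the files. Probe positions are those of the files, in mouse build mm9. A probe was kept if well above background on all 4 arrays in the 15p channel or on all 4 in the 0p channel (21658 probes). The brightest probe stood for its gene (17374 genes). Among 3590 genes with several kept probes, the mean log2 ratios of the probes differed by a median of 0.056, and by 1 or more for 0 genes. These differences do not show that probes agreed, because the ratios were small themselves. Over all tested genes their SD was 0.076 and their range -0.59 to 0.47. No gene was well above background on all arrays in one RNA and on none in the other, so no bound on a fold was needed.

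Ratios were turned to 15p over 0p and the arrays of a dye-swapped pair were averaged, which gave 2 replicate values per gene and cancels a dye effect that is equal on both arrays. These were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. Values are given as mean log2 ratio ± SD over 2 replicates. This SD leaves out the difference between the arrays of a pair, so a small SD does not show that single arrays agreed. Gene lists, 33 in all, were tested with camera on the same values (preset correlation 0.01, adjusted over the lists), and 31 had at least 3 tested members. They covered markers of hair follicle and epidermal identity, signalling and stress pathways, metabolism, and markers of other skin cell types. The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined, except the fits without 1 array and with crossed pairing, which were added after. The rule takes up to 12 called genes in each direction with the same sign on all 4 arrays, then for each list up to 4 called members with the largest ratios, or where none was called up to 2 that are said not to have passed. It always names Cd34, Itga6, Krt5, Krt14, Krt15, Trp63, Sox9, Lgr5, Lhx2, Axin2, Lef1, Mki67, Cdkn2a, Cdkn1a, Krt1, Krt10, Ivl, Vim, Ptprc, Pecam1 and Col1a1. Where few genes passed, genes at least 2-fold changed in both replicates were to be added, and there were 0. Of the genes that this rule takes, 1 is not reported here.

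Each replicate was run on a slide of its own, so slide and replicate cannot be told apart, and the replicate values are also the values within each slide. Whether the replicate numbers pair the arrays was checked by the correlation across genes of same-numbered arrays' deviations from the mean of their dye orientation. It was -0.26, where arrays more alike within a replicate would give a positive value. The check therefore did not bear the pairing out. The pairing rests only on the titles and on the shared slide. With 4 arrays limma's duplicateCorrelation gave no value for 2 coefficients, so the fit with the replicate as a block took its correlation (-0.33) from pooled, trimmed mean squares between and within replicates.

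The limma fits and camera were tested on simulated gene ratios with the estimated dye effects and noise drawn from the spread fitted over all genes. Background correction and normalisation were not simulated. All 4 arrays were given noise of 1 size, though 1 array had a wider spread of ratios (SD 0.29 against 0.13 to 0.14). The recovery below therefore describes the tests under that noise and not these arrays. Of 50 genes simulated at each fold, the main test recovered 22.0% at 1.2-fold and 100% at 1.5-fold, 2-fold and 4-fold among 17374 genes, with 6 false calls. All 3 lists simulated with a shift of 0.3 were called and 0 others. The largest list mean found in the data was 0.063, and genes were simulated as independent. Shifts of that size and correlation within a list were therefore not tested. The alternatives were 2 other background corrections, Agilent's processed signals, the value table, median centring, quantile normalisation of intensities between arrays, other filters on dim probes, the mean over a gene's probes, each dye orientation alone, the replicate as a block, separate channels, a trended robust variance, a fold threshold of 1.5, other set tests and each replicate left out. Signal over background sets what could be measured: median spot intensity was between 79.6 and 138.1, against medians of 47.5 to 75.2 for negative controls. The RNA was not compared with any other tissue, and no measurement of the protein CD34 was used here.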

Results

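Transcript levels were measured in mouse skin epithelial cells of the adult C3H/HeN strain, sorted for the surface proteins CD49f (integrin alpha 6) and CD34, which together mark stem cells of the hair follicle bulge. The 0p cells were sorted from primary skin epithelial cells, and the 15p cells were sorted after the 15th of a series of cultures in the presence of the growth factor Wnt-3a. The labels list Wnt-3a as the treatment of both RNAs, and whether the 0p cells were also cultured with it before their RNA was taken is not settled here. Each culture lasted 10 days in 60-mm collagen-coated dishes, and CD49f+ CD34+ cells were sorted again before the next. The comparison addressed how far the expression profile of the cells differed between the start and the end of this serial culture. Both RNAs were hybridised together on each of 4 whole-genome arrays, 1 with Cy5 and 1 with Cy3. There were 2 biological replicates, each run on 2 arrays with the dyes exchanged, so every value below rests on 2 replicate means (n = 2). The share of spots well above background was 59.3% in Cy5 and 57.0% in Cy3 on the array of replicate 1 with 15p in Cy5, and 59.8% and 55.5% on its dye swap. In replicate 2 these shares were 58.6% and 58.3% with 15p in Cy5, and 68.3% and 65.1% on the dye swap. The number of arrays limits the precision.

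Of 20 genes listed for basal keratinocyte adhesion, 18 were well above background in both 15p and 0p cells on all 4 arrays, with mean log2 ratios of 15p over 0p from -0.10 to 0.20. Krt5, a keratin of basal keratinocytes, had a ratio of 0.00042 ± 0.036 (SD, n = 2), and Trp63, a transcription factor that maintains stratified epithelia, had -0.026 ± 0.018. Its 95% interval ran from -0.15 to 0.094, and that of Krt5 from -0.12 to 0.12. Itga6, which encodes the sorted protein CD49f, had a ratio of 0.025 ± 0.041. No gene was called higher in 15p cells and none was called lower (0 of 17374 genes in each direction, limma with Benjamini-Hochberg adjustment at 0.05; lowest adjusted p = 0.749). At an unadjusted p under 0.05 there were 1095 genes, or 6.30% of those tested. No gene was at least 2-fold higher in both replicates and none was at least 2-fold lower, counts made without a test (0 and 0).

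**Figure D1:**
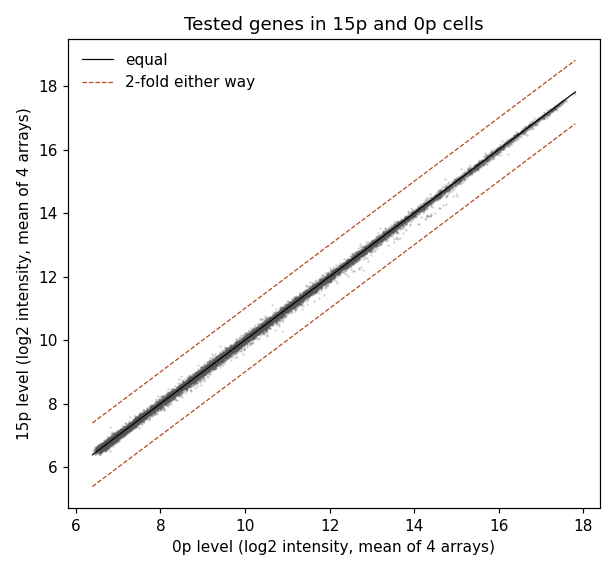
Level of each of the 17374 tested genes in 15p cells (vertical axis) against 0p cells (horizontal axis), as log2 intensity averaged over 4 arrays, with 1 point per gene. The solid line marks equal levels and the dashed lines a 2-fold difference, and the points lie along the solid line.

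The interval around each ratio was narrow, with a spread that limma moderates over all genes. The 95% interval lay within 1 log2 unit of 0 for 17373 genes (99.99%) and within a 1.5-fold difference for 17316 (99.7%), with a median half-width of 0.12. Mean log2 ratios ran from -0.59 to 0.47. Fits with a replicate block and a dye term (863 genes at an unadjusted p under 0.05) or with separate unpaired channels (44 genes) also called 0 genes. Fits of 3 arrays with a dye term, chosen after the data were seen, called 42 genes higher and 46 lower without the replicate 2 array with 15p in Cy5, and 1535 and 1585 without the replicate 1 array with 15p in Cy5. Both rest on prior degrees of freedom estimated as infinite, which gives all genes 1 common spread, and the array alone in its dye orientation adds nothing to that spread, so these counts have no replicate check of that array. Without 1 of the arrays with 15p in Cy3 the counts were 0 and 1 (replicate 2) and 0 and 0 (replicate 1). That 1 gene was Rtn4, which encodes an endoplasmic reticulum shaping protein and is named here after its value was seen. It had -1.05 and -0.63 in replicate 1, -0.72 on the replicate 2 array with 15p in Cy5, and 0.034 on the array left out. Rtn4 was also called lower without the filter on dim probes (-0.59 ± 0.35, adjusted p = 0.0154 against 0.749 with the filter). Prior degrees of freedom were 18.4 without the filter and 8.89 with it.

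The sort marker Cd34 was close to background in both RNAs. Of its 2 probes, 1 was well above background on 1 array, in the 0p channel, and the other on none, with Cy5 signals between 52.5 and 81.3. Median signals of negative control spots were between 47.7 and 50.7 in Cy5. Lgr5, a marker of cycling follicle stem cells, Lhx2, a transcription factor of the bulge, Axin2, a target of Wnt signalling, and Krt1, an early differentiation keratin, were not well above background on any array (0 of 4 in either RNA). Lef1, a mediator of Wnt signalling, was above background on 1 array in each RNA. Ptprc, a leukocyte gene, and Col1a1, a fibroblast collagen, were above it on 3 arrays in each RNA. No ratio is given for these 8 genes.

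Among the bulge stem cell markers, none of 17 tested members passed, whether adjusted over all genes or adjusted over the list alone. Tcf7l1 entered this list by its alias Tcf3 (0.13), a symbol that may stand for another gene. Krt15 (mm9 chromosome 11, 99993331 to 99993390), a keratin of the bulge, had a log2 ratio of 0.17 ± 0.033, and Sox9 (mm9 chromosome 11, 112648809 to 112648868), a transcription factor of follicle stem cells, had -0.38 ± 0.60. The Sox9 ratio came from 1 array: it was -1.56 on the replicate 2 array with 15p in Cy5 and -0.053 on the dye swap of the same RNAs, and 0.038 in replicate 1. Of 74 tested genes that the fixed rule takes, 49 had their largest absolute ratio on that array. Many of these genes were taken for the size of a mean that includes that array, so the rule itself favours this count. For basal keratinocyte adhesion, 0 of 18 members passed by either adjustment; Cdh3, which encodes P-cadherin, had 0.20 ± 0.17 and Krt14 (mm9 chromosome 11, 100064683 to 100065288) 0.19 ± 0.12. Krt14 had 0.73 on the replicate 2 array with 15p in Cy5, against -0.18 on its dye swap and 0.085 and 0.12 in replicate 1. Cdh3 had positive ratios on both arrays with 15p in Cy5 (0.45 and 1.10) and negative ratios on both dye swaps (-0.28 and -0.45). Krt5 showed the same split by dye, with 0.23 and 0.34 against -0.18 and -0.39. So did Krt15, with 0.31 and 0.48 against -0.012 and -0.093. Among 18 tested genes of epidermal terminal differentiation, Tgm1, a crosslinking enzyme of the cornified envelope, had 0.20 ± 0.13 and Ppl, an envelope plakin, -0.16 ± 0.24. Krt10 had -0.017 ± 0.013 and Ivl, which encodes involucrin, -0.025 ± 0.0033, and neither passed. The stress keratins Krt6a (0.16 ± 0.035) and Krt16 (0.14 ± 0.052), both known from wounded and cultured epidermis, did not pass either. Members of the hair shaft and inner root sheath list (Krt72, -0.14 ± 0.12, and Msx2, 0.12 ± 0.079) and of the sebaceous gland list (Plin2, 0.067 ± 0.056, and Dgat2, 0.063 ± 0.037) stood within the same range.

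**Figure D2:**
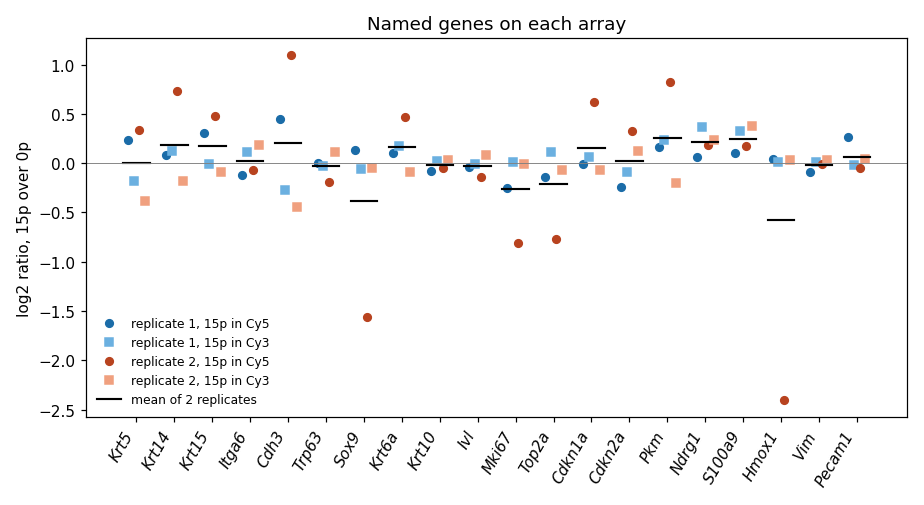
Log2 ratio of 15p over 0p (vertical axis) for 20 named genes (horizontal axis) on each of the 4 arrays, with circles for 15p in Cy5, squares for 15p in Cy3 and a bar for the mean of 2 replicates. The replicate 2 array with 15p in Cy5 gave the lowest values of Hmox1 (-2.40) and Sox9 (-1.56), while the other 3 arrays lay between -0.059 and 0.14 for Sox9.

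Proliferation and growth arrest genes did not pass in either direction. Mki67 (mm9 chromosome 7, 142881591 to 142881650), a marker of cycling cells, had a log2 ratio of -0.27 ± 0.20, and Top2a, the topoisomerase of dividing cells, -0.21 ± 0.29. Both leaned on the replicate 2 array with 15p in Cy5, which gave -0.81 for Mki67 and -0.77 for Top2a, against -0.0077 and -0.067 on its dye swap. Of 29 tested cell cycle genes 14 had positive and 15 negative ratios, and the list mean was -0.021 (camera, adjusted p = 0.698). Cdkn1a, the p53-induced cell cycle inhibitor p21, had 0.15 ± 0.18, Ccng1, another p53 target, -0.15 ± 0.11, and Cdkn2a, the inhibitor that accumulates in senescent cells, 0.027 ± 0.28. The Cdkn1a ratio came from the replicate 2 array with 15p in Cy5 (0.62), with -0.070 on its dye swap and -0.011 and 0.060 in replicate 1. The list of cell cycle inhibitors, p53 targets and senescence genes had a mean of 0.023 over 21 genes (adjusted p = 0.698).

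Genes of glycolysis and hypoxia had a higher mean in 15p cells than other genes, the only list of 31 tested that camera with a preset correlation of 0.01 called. Their mean log2 ratio was 0.062 over 21 genes (adjusted p = 0.0131), and 16 had positive and 5 negative ratios. The call was not made with an estimated correlation (adjusted p = 0.985) or with fry, which tests the list without other genes (adjusted p = 0.578). With 1 residual degree of freedom, camera with an estimated correlation gave no list a lower adjusted p than 0.985. Its missing call therefore cannot weigh against this list. By array the mean was 0.097 and 0.039 in replicate 1, and 0.12 and -0.010 in replicate 2, with 15p in Cy5 first. No member passed over all genes, and 2 passed when adjusted over the list alone. These were Pkm (mm9 chromosome 9, 59526867 to 59526926; 0.26 ± 0.077), which encodes a pyruvate kinase, and Ndrg1 (mm9 chromosome 15, 66761057 to 66761116; 0.21 ± 0.0040), a gene induced by low oxygen. Pkm had 0.83 on the replicate 2 array with 15p in Cy5, -0.20 on its dye swap, and 0.17 and 0.24 in replicate 1. Ndrg1 was positive on all 4 arrays.

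Other metabolic lists were not called. Cholesterol synthesis genes had a mean of 0.047 over 23 genes, 17 of them positive (camera, adjusted p = 0.139), with Srebf2, a transcription factor of sterol synthesis, at 0.19 ± 0.38 and Dhcr7, the last enzyme of the pathway, at 0.15 ± 0.12. Genes of the oxidative stress response had a mean of -0.020 over 19 genes (adjusted p = 0.982). Hmox1 (mm9 chromosome 8, 77624207 to 77624266), heme oxygenase, had -0.58 ± 0.86, from -2.40 on the replicate 2 array with 15p in Cy5 and 0.037 on its dye swap. Slc7a11, a cystine transporter, had -0.20 ± 0.21.

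Signalling lists had means between -0.015 and 0.042, and camera called none of them. Wnt/beta-catenin target genes had a mean of 0.015 over 10 tested genes (adjusted p = 0.743), with Tcf7 at 0.063 ± 0.048 and Ephb3 at -0.049 ± 0.15. For Notch signalling the mean was 0.037 (adjusted p = 0.45), with Hes1, a Notch target, at 0.14 ± 0.019 and the receptor Notch3 at 0.13 ± 0.056. For Hedgehog signalling the mean was 0.042 (adjusted p = 0.45), with the receptor Ptch1 at 0.088 ± 0.059. BMP signalling had 0.021, with Id1 at 0.11 ± 0.096 and Id2 at -0.096 ± 0.040. EGF receptor ligands and signalling had -0.015, with Areg, a ligand of the receptor, at -0.14 ± 0.17 and Errfi1, its feedback inhibitor, at -0.11 ± 0.13. Immediate early and heat shock genes had 0.015, with Ier2 at 0.18 ± 0.12 and Fosb at 0.14 ± 0.099.

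Inflammation and antimicrobial genes had a mean of 0.0011 over 16 genes. S100a9 (mm9 chromosome 3, 90496573 to 90496632), a subunit of calprotectin, had 0.25 ± 0.043 and was the only member that passed when adjusted over the list alone, though not over all genes (adjusted p = 0.749). It was positive on all 4 arrays. Apart from Pkm, Ndrg1 and S100a9, no member of any list passed when adjusted over the list alone. Ptgs2, which encodes cyclooxygenase, had -0.13 ± 0.034. Interferon response genes had a mean of 0.018 over 19 genes, with Oasl2 at 0.14 ± 0.12 and Usp18 at 0.13 ± 0.050. Lists of epithelial-mesenchymal transition (0.0022; Tgfb1, 0.12 ± 0.083, and Fn1, -0.096 ± 0.098) and of epithelial junctions (-0.010; Cldn4, -0.18 ± 0.65, and Dsp, -0.14 ± 0.19) were not called. Vim, a mesenchymal filament gene, had -0.014 ± 0.037. Chromatin regulators had 0.011, with Kdm6b at 0.17 ± 0.12 and Hdac2 at -0.15 ± 0.14, and pluripotency factors had -0.015, with Lin28b at -0.088 ± 0.087 and Tfcp2l1 at -0.072 ± 0.0090. The means of the identity lists were 0.0093 for bulge stem cell markers, 0.013 for basal keratinocyte adhesion, 0.025 for terminal differentiation, 0.018 for hair shaft and inner root sheath, 0.010 for sebaceous gland, and 0.057 for simple epithelium and stress keratins. The keratin mean leaned on the replicate 2 array with 15p in Cy5 (0.22), against -0.014 on its dye swap and -0.0027 and 0.022 in replicate 1. The median, the mean or the camera direction differed in sign for the lists of inflammation, oxidative stress, basal keratinocyte adhesion, epithelial-mesenchymal transition, epithelial junctions, endothelial, immune and melanocyte genes.

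Of the lists of markers of other skin cell types, between 2 and 7 members each were tested and none passed, over all genes or adjusted over the list alone. Means were 0.029 for 4 tested dermal fibroblast genes (Col3a1, 0.088 ± 0.044; Twist2, 0.030 ± 0.048), -0.0015 for 6 endothelial genes (Flt1, -0.13 ± 0.14; Eng, 0.088 ± 0.23; Pecam1, 0.060 ± 0.086) and -0.00067 for 7 immune genes (Fcer1g, -0.060 ± 0.095; H2-Eb1, 0.055 ± 0.12). Melanocyte genes had 0.0050 (Mlana, 0.083 ± 0.020; Mitf, -0.044 ± 0.031), Schwann cell and nerve genes -0.017 (Ncmap, -0.12 ± 0.031; Prx, 0.064 ± 0.047) and skeletal muscle genes 0.042 (Mb, 0.17 ± 0.081; Pvalb, 0.11 ± 0.067). Erythroid genes had 0.063 over 3 genes (Hba-a2, 0.11 ± 0.085; Hba-a1, 0.10 ± 0.085, near-identical copies whose probes may not tell them apart) and Merkel cell genes 0.0044 (Krt8, 0.030 ± 0.062; Snap25, -0.026 ± 0.12). Camera called none of these 8 lists. Mast cell (Tpsb2, -0.072 ± 0.0059; Mrgprb1, 0.037 ± 0.0052) and adipocyte genes (Lipe, -0.044 ± 0.088; Adrb3, 0.017 ± 0.043) had 2 tested members each and were not tested as lists. Tpsb2 had 0.11 on both arrays with 15p in Cy5, and -0.26 and -0.25 on the dye swaps, a split that its SD leaves out.

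**Figure D3:**
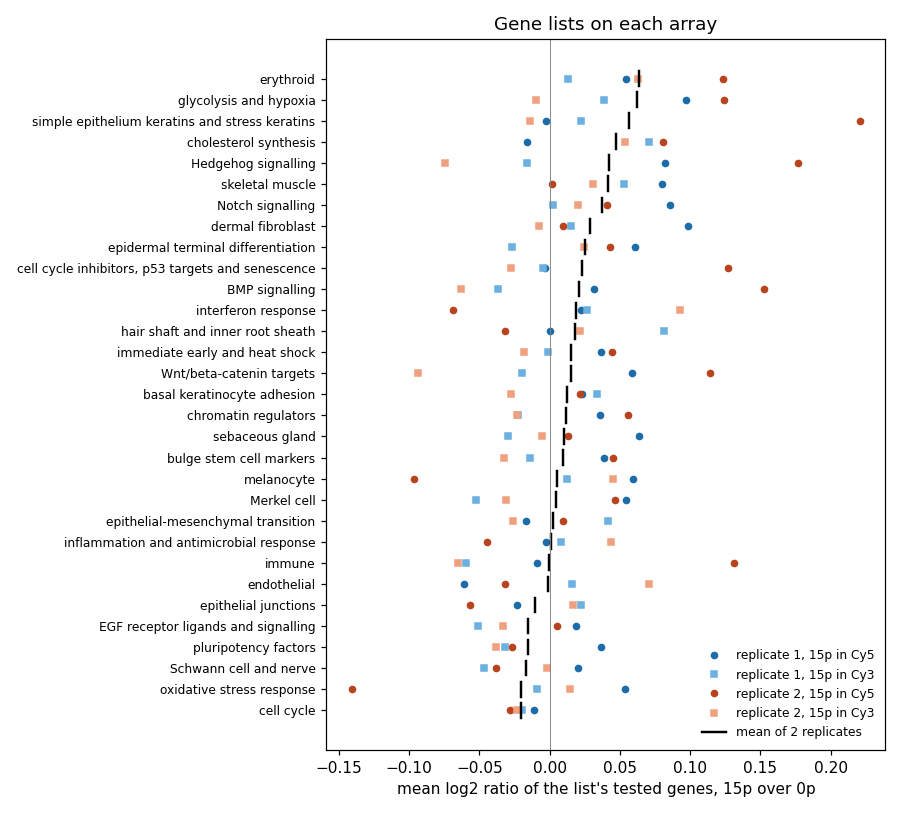
Mean log2 ratio of 15p over 0p (horizontal axis) of the tested members of each of 31 gene lists (vertical axis) on the 4 arrays, with circles for 15p in Cy5, squares for 15p in Cy3 and a bar for the mean of 2 replicates. Bars lie between -0.021 for cell cycle genes and 0.063 for erythroid genes, and single arrays spread wider than the bars.

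Ratios of 15p over 0p were weakly correlated between the replicates, with a sign that turned without 1 array. Across 17374 genes, which are not independent replicates, the dye-averaged ratios of the replicates had a Pearson r of 0.089 and a Spearman rho of 0.17. Without the replicate 2 array with 15p in Cy5 the r was -0.057, with replicate 2 on 1 array, where a dye effect does not cancel. Within a dye-swapped pair the ratios of 15p over 0p ran opposite, with r = -0.55 in replicate 1 and r = -0.40 in replicate 2. The ratio of Cy5 over Cy3 was thus shared between arrays that, per the labels, carried the RNAs in opposite dyes. Krt5 and Cdh3 are named examples above. The SD of log2 ratios across genes was 0.14 and 0.13 on the arrays of replicate 1, and 0.29 with 15p in Cy5 and 0.14 with 15p in Cy3 in replicate 2. On that array of replicate 2, 108 genes were beyond 2-fold, against 4, 0 and 3 on the others.

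**Figure D4:**
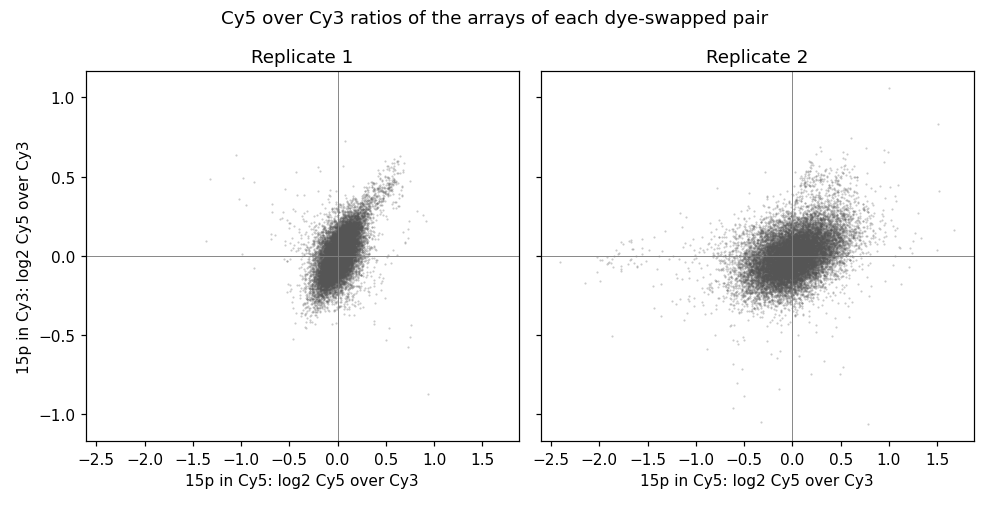
Log2 ratio of Cy5 over Cy3 for each tested gene on the array with 15p in Cy3 (vertical axis) against the array with 15p in Cy5 (horizontal axis), with 1 panel per replicate and 1 point per gene. Points rise from lower left to upper right (r = 0.55 and 0.40). With the dyes exchanged as labelled, a difference between 15p and 0p would place them from upper left to lower right.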

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

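Control spots for spike-in RNA stood above the negative controls on 1 array. On the array of replicate 2 with 15p in Cy3, the 320 spots had a median intensity of 78.6 in Cy5 and 78.8 in Cy3, against 57.7 and 68.7 at the 95th percentile of the negative control spots. On the other 3 arrays the spike-in medians were below that percentile in both dyes. These spots entered no comparison of the report, and no explanation was tested.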

How the results depend on the processing

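The fits without 1 array and with crossed pairing were chosen after the data were seen. The count of 0 called genes was kept in 13 of 20 alternative fits, the replicate block included (0 higher, 0 lower). These 13 were not separate checks. The fit with a fold threshold cannot call a gene that the main test does not call. Quantile normalisation of intensities nearly repeated the main fit (1097 against 1095 genes at an unadjusted limma p under 0.05). Processed signals and the value table hold nearly the same ratios (923 and 917 genes). Separate channels dropped the pairing of both RNAs on an array (44 genes). No gene was 2-fold in both replicates under any of 15 alternatives. Without a filter on dim probes 1 gene, Rtn4, was called lower. Arrays with 15p in Cy5 alone called 17 genes higher and 47 lower, and arrays with 15p in Cy3 alone 229 and 591; in these fits no dye effect cancels by construction. They turned Krt5 (-0.28), Cdh3 (-0.36) and Flt1 (0.23) on the arrays with 15p in Cy3. With 1 array left out and a dye term, 42 genes were called higher and 46 lower without the replicate 2 array with 15p in Cy5, 1535 and 1585 without that of replicate 1, 0 and 1 (Rtn4) without the replicate 2 array with 15p in Cy3, and 0 and 0 without that of replicate 1. By construction the spread in these fits comes only from the 2 arrays that share a dye orientation. Crossed pairing called 7 and 53, and the cause was not tested. The prior degrees of freedom were infinite in the fits with 42, 1535 and 7 higher calls and with 15p in Cy3 alone, against 8.89 with all arrays averaged by replicate, so those calls take 1 spread for all genes and may be too many. Glycolysis and hypoxia kept its call in 13 of 17 tests. Camera with an estimated correlation, 1 of those without a call, called no list at all (lowest adjusted p = 0.985) and cannot weigh against it. Fry, among those without a call, tests the list against no change and not against other genes (adjusted p = 0.578). Its shift against other genes was 0.10 with 15p in Cy5 alone (adjusted p = 0.495) and 0.024 with 15p in Cy3 alone (adjusted p = 0.853), where it was not called (the cause was not tested), and 0.062 with an estimated correlation (adjusted p = 0.985). Its adjusted p over the alternatives ran from 0.000161 to 0.985. Leaving out a replicate gave 0.057 and 0.067, values with no test; calls of single genes then have no test either. Cholesterol synthesis was called after median centring (shift 0.062, adjusted p = 0.0127; range over alternatives 0.0127 to 0.985), and simple epithelium and stress keratins with the mean of a gene's probes (0.077, adjusted p = 0.0487; range 0.0487 to 0.985); the cause was not tested. The other lists stayed uncalled in 17 tests each. The r between replicates was 0.27 with 15p in Cy5 alone, 0.41 with 15p in Cy3 alone and -0.057 without the replicate 2 array with 15p in Cy5. Within the pair of replicate 1, r was -0.49 with normexp offset 16, -0.39 with processed signals and with the value table, -0.93 with median centring, -0.44 without a filter, -0.57 with the strict filter and -0.52 with the mean of probes. In replicate 2 these were -0.38, -0.35, -0.35, -0.67 and -0.36, with -0.38 for the mean of probes. Signal over background limits Cd34, Lgr5, Lhx2, Axin2 and Krt1, which no setting with a filter could test.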

Other observations

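Across all tested genes, 24 had the same sign of 15p over 0p and a log2 ratio of at least 0.1 on every array, 14 higher and 10 lower, and they were chosen after their values were seen. None passed the limma test (adjusted p = 0.749 for each). Ly6d (0.35 ± 0.11), a surface antigen of stratified epithelia, Ddit4 (0.35 ± 0.19), a stress-induced inhibitor of mTOR signalling, Akt1s1 (0.32 ± 0.25), a component of mTOR complexes, and Spr (0.31 ± 0.099), an enzyme of tetrahydrobiopterin synthesis, had the largest positive ratios with a gene symbol (SD, n = 2). Entpd3 (0.20 ± 0.039) and Eya2 (0.22 ± 0.10) were also positive, and Fzd5 (-0.16 ± 0.030), a Wnt receptor, and Mknk1 (-0.20 ± 0.077), a kinase of translation factors, were negative. Crossing the sign of one replicate gave 20 genes by the same criterion, and the ratio of Cy5 over Cy3 gave 1138. With the sign of Cy5 over Cy3 turned on 1 slide there were 71. Over all genes, 6.78% kept one sign of 15p over 0p on 4 arrays, and 4.58% with 1 replicate crossed. For Cy5 over Cy3 the share was 32.3%, and 13.5% with 1 slide turned. Independent signs would give 12.5%.

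In the 3 patterns that follow, the tests of probe base composition were written before their results were seen, and all others after.

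The ratio of Cy5 over Cy3 was shared by the arrays of each dye-swapped pair (r = 0.55 and 0.40 across genes), as for Krt5 and Cdh3. If a dye swap had not been made and real changes were read as dye, different probes of a gene should agree too, with a correlation taken here to be at least 0.2 times that of the same probe. In replicate 1 this ratio of the cross-probe to the same-probe correlation was 0.068 (95% bootstrap interval 0.011 to 0.12). This argues against real changes as a large part of the shared ratio there. Small changes beneath a dye bias would give a low ratio whether or not the swap was made, so an unmade swap is not excluded. In replicate 2 the ratio was 0.26 (0.19 to 0.32), an interval that spans 0.2 and leaves an unmade swap open. A dye bias of single probes could give this pattern, but base composition of the probe explained only 0.015 and 0.046 of the variance on a slide not used for the fit, too little to decide.

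The Cy5 channel of the replicate 2 array with 15p in Cy5 stood apart (r of 0.994 to 0.995 with the other 7 channels, which correlated at 0.996 to 0.999 among themselves), with Hmox1 and Sox9 among 82 genes beyond 2-fold lower and 26 higher. Of these 108 genes 29 had the same direction on the dye swap, and the slope of the swap on this array was -0.054 (-0.078 to -0.034), which argues against a 15p change in replicate 2. Replicate spots of 243 probes agreed (intraclass correlation 0.96, 0.94 to 0.97), against a spatial defect, and base composition explained 0.071 of the variance (0.065 to 0.078), against base composition as the main cause. A difference in the labelled RNA of this hybridisation may remain, and was not tested.

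No gene passed between 15p and 0p cells, with Krt5, Trp63 and Itga6 at similar levels. With the dye swaps made as labelled, the interval lay within 1 log2 unit of 0 for 99.99% of genes. This argues against too little precision for 2-fold changes in measured ratios. It cannot exclude 2-fold changes in the RNA of dim genes, because the normexp offset of 50 shrinks the ratios of dim spots. Interval widths also rested mostly on the spread pooled over all genes (prior degrees of freedom 8.89, residual 1). The same RNA in both dyes was taken here to leave no link between replicates, a premise that was not tested. One probe's ratio in replicate 1 correlated weakly with another probe's of the same gene in replicate 2 (r = 0.043, 95% bootstrap interval 0.012 to 0.072, dye ratios regressed out). This link was not computed without the replicate 2 array with 15p in Cy5, without which the r between replicates turned negative. The test therefore cannot decide whether both dyes held the same RNA. A swap not made, left open above in replicate 2 (0.26, 0.19 to 0.32) and for small changes in replicate 1, would cancel real changes in that replicate's mean. On a single array it would turn the sign and not the size. Beyond 2-fold were 4 and 0 genes on the arrays of replicate 1, and in replicate 2 108 with 15p in Cy5 and 3 on its dye swap. These counts argue against many 2-fold differences in measured ratios however the swaps were made. The size of smaller differences between 15p and 0p cells, and of differences in dim genes, stays open.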
